A study of Escherichia coli K-12 with 45 samples.

How the data were processed

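RNA-seq was made from Escherichia coli K-12 NCM3722 and strains derived from it. Per the labels' protocols, RNA was extracted with TRIzol, ribosomal RNA was removed with Ribo-Zero and libraries were built with the TruSeq kit. Per the submitters' processing notes, reads were processed with cutadapt, Bowtie2 2.2.6 and HTSeq 0.6.1p2. The genome build, the annotation, whether counting used strand and any filter were not stated in the sources used here. The deposited values are fractions, given by the authors as 1 column per library, and the number of reads behind them was not stated. Each column sums to 1 over 4342 genes. Per column, 98.4% to 99.95% of values above 0, times the gene length listed by the authors, lay within 0.01 of a whole multiple of 1 step, so the fractions were taken as shares of transcripts after division by gene length. Counts were not inferred from these steps, and depth is treated as unknown. The values are given in ppm of all transcripts. Growth rates per h were listed by the authors, and how they were measured was not stated.

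Samples were grouped by the labels. The steady-state table gave 28 libraries in 15 groups, 13 groups with 2 biological replicates and 2 groups, a3 and r5, with 1. Its columns named a4_1 numbered 2 and were identical in all genes, and 0 were named a3_1. The second of them, 1 column, was not used, so the second a3 library was not analysed here and the plan of 29 libraries became 28. The rifampicin table gave 16 libraries, 8 time points for each of 2 courses. Loci matched the NCBI gene table of assembly ASM584v2 (strain MG1655) for 4250 of 4342 genes, with another symbol in 183 of these, and 92 did not match, 18 of them with the locus 0. Since no build was named, that table was used for names and for the order of neighbouring genes alone, and symbols are those of the deposited table.

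Steady-state levels were compared as log2 of ppm plus a pseudocount of 1 in a single limma fit (limma 3.58.1 in R 4.3.3, trended empirical Bayes variances) with a mean per group and 13 residual degrees of freedom. Genes with a mean of at least 5 ppm, 3279 in all, were tested, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. The comparisons were c4 with M9, a4 with M9, r4 with MOPS, MOPS with M9 and c4 with a4, and the differences of changes between R- and C- and between R- and A-limitation. The slowest condition with 2 libraries stood for each limitation. Within a limitation, log2 levels were regressed on growth rate with limma. Rifampicin levels of 2744 genes were regressed on time with an intercept and a slope per course over 16 libraries, and the difference of slopes was tested. Overlap between the C- and A-limitation, which share the M9 libraries, was set against 100 simulations of unchanged groups with the same shared libraries.

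Before the data were examined, 26 gene lists were written from general knowledge of E. coli genes, and with them the comparisons, the tests, the filter, the rule for named genes and most alternatives. The list of stable non-coding RNAs had 0 of its members in the table, and the list of engineered targets holds 3 genes, so 24 lists were tested. They cover ribosomal proteins, translation factors, aminoacyl-tRNA synthetases, hibernation and rescue factors, flagella and chemotaxis, and CRP-linked carbon genes. They also cover glycolysis, the TCA cycle, acetate metabolism, RpoS-associated genes, NtrC/Nac genes, ammonium assimilation, amino acid biosynthesis, and purine and pyrimidine synthesis. The rest are heat shock, cold shock, RNA degradation, RNA polymerase, nucleoid proteins, respiration, porins, drug efflux, the SOS response and iron acquisition. Lists were tested with camera at a preset correlation of 0.01 and at an estimated one, and with fry. Shares of each list were correlated with growth rate over libraries by Pearson's r and Spearman's rho. Their p came from exact permutation tests with fewer than 10 libraries and from 100000 permutations otherwise, all two-sided and adjusted over 72 relations.

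Named genes followed a rule. The engineered targets ptsG, gltB and gltD were always named. Per comparison, the 10 largest rises and 10 largest falls were named among genes past the threshold with a mean of at least 20 ppm and libraries of both groups apart. From each list described, up to 4 passing members with the largest change could be named, or up to 2 abundant ones where none passed. From the rifampicin courses, the 10 lowest and 10 highest slopes of the reference course and up to 5 slope differences per direction were named. The genes rsd, rne, rpoB, rpoC, rpoD and rpoS completed the rule, and ssrS was not measured. The code was tested on simulated data with 200 changed genes. For the C-, A- and R-limitation 98.0% of log2 changes of 2 were recovered in each, and 67.0%, 70.0% and 66.7% of changes of 1, with 4.68%, 7.22% and 4.12% of calls false. For MOPS with M9 98.0% and 69.0% were recovered (6.18% of calls false), and for c4 with a4 99.0% and 71.7% (3.95% false). For growth-rate slopes of 2 and 1, 87.0% and 33.0% were recovered in the C-, 90.0% and 21.4% in the A- and 83.8% and 33.0% in the R-limitation, with 4.00%, 3.48% and 10.1% of calls false. For a difference of decay slopes of 0.4 and 0.2 per min 52.0% and 18.0% were recovered, with 10.3% of calls false.

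Alternatives were other pseudocounts and filters, median-of-ratios scaling, removal of the 10 most abundant genes and a fit on 2 groups alone. Others were a sequencing set term (by title), other references and conditions, fewer time points, and each library or time point left out. Shares, permutations and figures were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.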

Results

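Transcript abundance of 4342 genes of Escherichia coli K-12 was measured by RNA-seq in 28 steady-state libraries from 15 culture conditions and in 16 libraries from 2 rifampicin time courses. The wild type, NCM3722, was grown in M9 medium and in MOPS medium, with 2 biological replicates each. In the C-limitation the glucose transporter gene ptsG was titrated through an inducible promoter in 4 conditions (c1 to c4, 2 libraries each). In the A-limitation the glutamate synthase operon gltBD was titrated with IPTG in 4 conditions (a1 to a4, 2 libraries each except 1 for a3). In the R-limitation the wild type in MOPS medium received chloramphenicol, an inhibitor of translation, at 5 doses (r1 to r5, 2 libraries each except 1 for r5). Growth rates of the slowest replicated conditions were 0.3 and 0.39 per h for c4, 0.24 and 0.34 per h for a4, and 0.4 and 0.28 per h for r4. The M9 cultures grew at 0.91 and 0.95 per h and the MOPS cultures at 0.89 and 0.91 per h.

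The deposited values were shares of all transcripts, given here in ppm, and the number of reads behind them was not stated. Between 83 and 117 genes were listed at 0 in a steady-state library and between 97 and 404 in a rifampicin library. The 10 most abundant genes held 12.4% to 20.7% of the transcripts in steady state and 12.99% to 67.1% after rifampicin. Replicates of the steady-state groups correlated across genes with r between 0.965 and 0.993 on the log2 scale, where genes are not independent replicates. Because the genome build behind the values was not stated, genes are identified by symbol and locus tag and no positions are given. Values are means ± SD over 2 libraries, and log2 changes are given ± SE from limma with Benjamini-Hochberg adjusted p.

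The titrated genes were examined first, since the labels name them as the point of control. In the C-limitation ptsG (b1101), the glucose-specific permease of the phosphotransferase system, was at 53.3 ± 18.05 ppm in c1, 38.01 ± 1.42 in c2, 62.4 ± 15.96 in c3 and 32.4 ± 20.5 in c4, against 1681 ± 306 in the M9 cultures. Its level was low in all 8 C-limited libraries and did not follow the growth rate from c1 to c4, where c1 and c2 are one titrated strain and c3 and c4 another. In the A-limitation gltB (b3212), the large subunit of glutamate synthase, was at 1226 ± 559 ppm in a1, 518 ± 93.9 in a2, 253 in the single a3 library and 199 ± 9.37 in a4, against 913 ± 21.6 in M9. The small subunit gene gltD (b3213) stood at 1065 ± 217, 478 ± 7.15, 231 and 190.4 ± 27.5 ppm in the same conditions and at 1248 ± 36.4 ppm in M9. In the R-limitation, where neither gene was manipulated, ptsG fell from 1679 ± 158 ppm in MOPS medium to 381 ± 137 ppm in r4 (log2 change -2.18 ± 0.37, limma adjusted p = 0.000206).

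**Figure D1:**
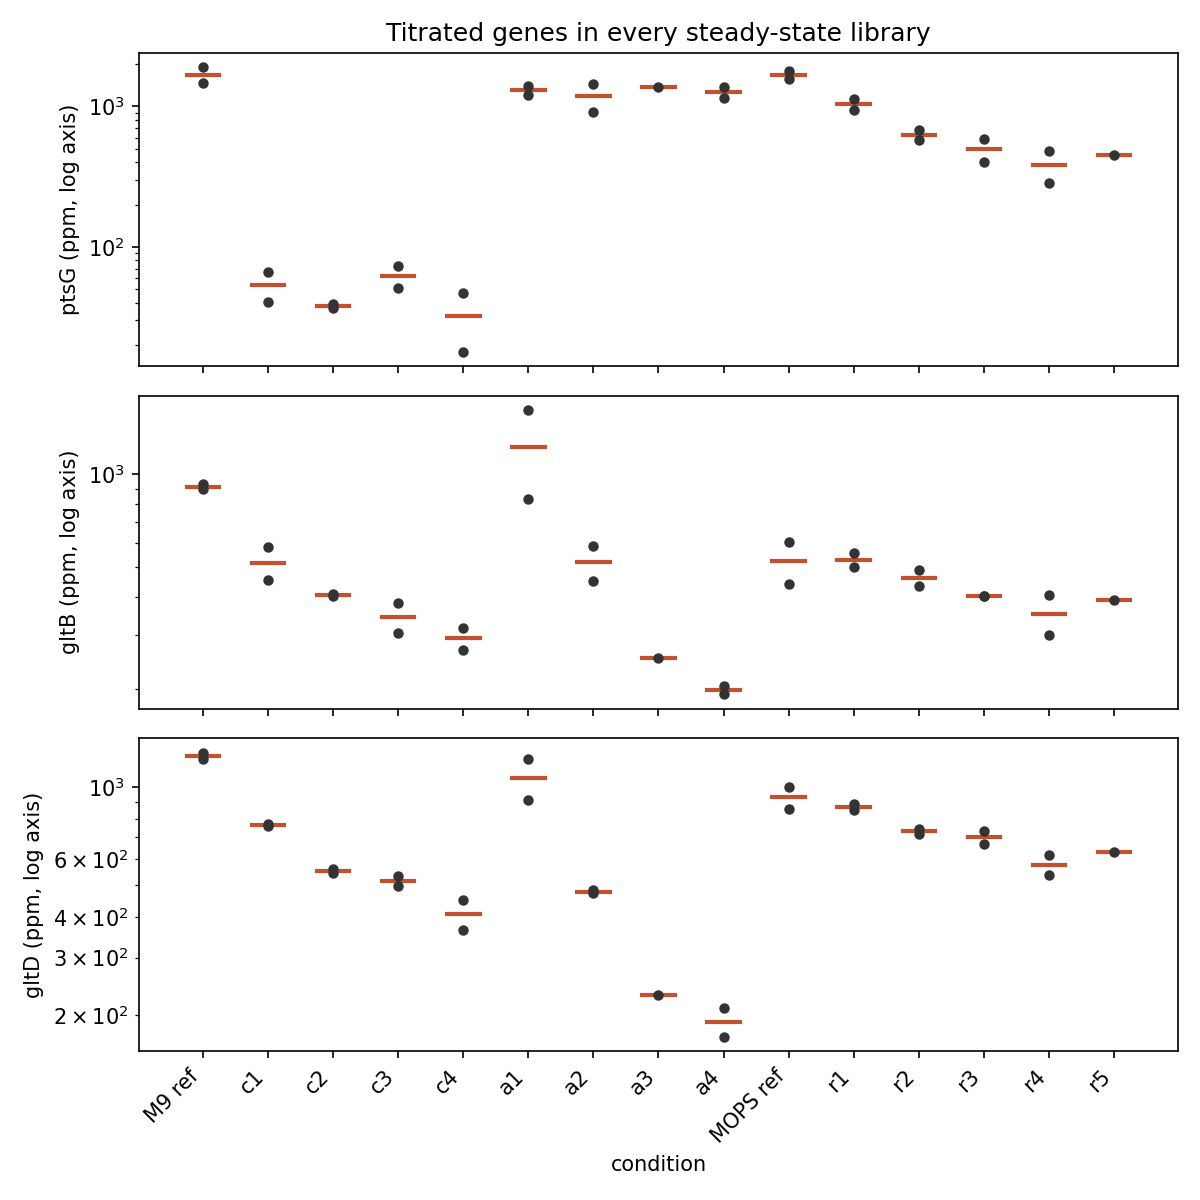
Levels of ptsG, gltB and gltD (ppm, log axis) in every steady-state library by condition, with points for libraries and bars for condition means. All 8 C-limited libraries lie below the M9 cultures for ptsG, and the gltB mean falls from 1226 ppm in a1 to 199 ppm in a4.

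Which transcripts changed when glucose uptake limited growth was asked by comparing c4 with the M9 wild type (n = 2 and 2). The maltose genes rose most. The outer membrane maltoporin gene lamB (b4036) was at 4682 ± 421 ppm against 11.7 ± 3.498 ppm (log2 change 8.56 ± 0.37, limma adjusted p = 8.67e-12). The periplasmic maltose-binding protein gene malE (b4034) was at 5226 ± 160.0 ppm against 23.4 ± 5.51 ppm (log2 change 7.76 ± 0.26, adjusted p = 1.37e-12). Log2 changes of the transporter genes malK, malG and malF and of the periplasmic protein gene malM were 7.74 ± 0.37, 7.26 ± 0.30, 7.22 ± 0.26 and 7.57 ± 0.31. The glycolate oxidase genes glcD and glcE rose by 6.23 ± 0.36 and 6.22 ± 0.37, the fatty acid oxidation gene fadB (b3846) by 6.21 ± 0.30 and yjcH, which lies beside the acetate permease gene, by 5.96 ± 0.27. Among falls, ptsG changed most (-5.79 ± 0.37, adjusted p = 1.1e-09). It was followed by the nitrite reductase gene nirB (-4.70 ± 1.06), the malate:quinone oxidoreductase gene mqo (b2210) (-3.40 ± 0.37), the nitrogen regulator gene glnK (-3.01 ± 0.41), nirD (-2.92 ± 0.95) and the NADH dehydrogenase gene ndh (b1109) (-2.60 ± 0.31). The methionine synthase gene metE (b3829) was at 1380.5 ± 391 ppm against 7724 ± 497 ppm (-2.51 ± 0.25), ybfA changed by -2.58 ± 0.42, and the ferrous iron transport genes feoA and feoB fell by 2.45 each on the log2 scale. Both glutamate synthase genes also fell, gltB by 1.64 and gltD by 1.62.

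Of 3279 genes tested with limma in this comparison, 1295 changed, 810 higher and 485 lower, and 495 and 182 of these changed at least 2-fold. Without M9 replicate 2 or c4 replicate 1 the lower genes numbered 305 and 319, and with c1 as the reference 731 genes changed, 542 higher and 189 lower. The median log2 change of all genes was 0.08. Under median-of-ratios scaling, which moved that median by -0.19, 648 genes were higher and 844 lower, so the share of changed genes that were higher went from 62.5% to 43.4%. With ribosomal protein and flagellar genes removed and the rest rescaled, a check added after the values were seen, 689 were higher and 810 lower. The libraries of c4 and M9 did not overlap for 69.2% of the tested genes, where chance gives 33.3%. The c4 strain differs from the wild type in its promoter and inducer as well as in growth rate.

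Among the lists fixed in advance, the maltose genes belong to the CRP-linked carbon list of 69 measured genes, of which 53 rose, 3 fell and 13 did not pass (55 and 3 adjusted over the list alone). The CRP-linked list had a median log2 change of 2.01 (camera adjusted p = 5.24e-20, 0.121 with an estimated correlation). Of 54 ribosomal protein genes, 0 rose, 45 fell and 9 did not pass (0 and 47 adjusted over the list alone), with rpsR, rplL, rplA and rplI at -1.25, -1.22, -1.22 and -1.21. Ribosomal proteins had a median log2 change of -0.94 (camera adjusted p = 5.7e-18, 0.157 with an estimated correlation). Among 92 amino acid biosynthesis genes 5 rose, 45 fell and 42 did not pass (5 and 47 adjusted over the list alone), with the aspartase gene aspA at 3.22, hisG of histidine synthesis at -2.16 and serA of serine synthesis at -2.08. Amino acid genes had a median log2 change of -0.54 (camera adjusted p = 3.15e-09, 0.359 with an estimated correlation). In the list of glycolysis and the phosphotransferase system 2 rose and 14 fell of 17 (2 and 14 adjusted over the list alone), with fbaB at 2.15, gpmM at -1.89 and eno at -1.80. The glycolysis list had a median log2 change of -1.11 (camera adjusted p = 2.94e-06, 0.359 with an estimated correlation). Without ptsG, which was titrated here, its median was -1.08 (camera adjusted p = 2.69e-05, adjusted p = 0.366 with an estimated correlation). The isocitrate lyase gene aceA (b4015) of the glyoxylate shunt was at 1778 ± 118 ppm against 62.6 ± 8.79 ppm (log2 change 4.81 ± 0.18), and aceK, aceB and fumC rose by 4.22, 4.19 and 2.74. In the TCA and glyoxylate list 15 rose and 0 fell of 18 (16 and 0 adjusted over the list alone). The TCA list had a median log2 change of 0.88 (camera adjusted p = 2.94e-06, 0.359 with an estimated correlation).

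For nitrogen and stress, the putrescine transport genes ydcS, ydcT and ydcV rose by 4.80, 4.53 and 3.82 and the amino acid transport gene argT by 3.47. In their NtrC/Nac list 24 rose and 10 fell of 43 (24 and 11 adjusted over the list alone). The NtrC/Nac list had a median log2 change of 1.43 (camera adjusted p = 0.00105, 0.359 with an estimated correlation). In the RpoS-associated stress list 18 rose and 1 fell of 32 (20 and 1 adjusted over the list alone), with the catalase gene katE at 2.37 and the trehalose synthesis gene otsB at 1.93. The RpoS list had a median log2 change of 0.91 (camera adjusted p = 0.000331, 0.366 with an estimated correlation). In the ammonium assimilation list 0 rose and 3 fell of 7 (0 and 3 adjusted over the list alone), with glutamine synthetase glnA at -1.95. The ammonium list had a median log2 change of -0.46 (camera adjusted p = 0.00837, 0.265 with an estimated correlation). Without gltB and gltD it did not pass camera (adjusted p = 0.178, median -0.15 over 5 genes), a test added later. Among purine and pyrimidine synthesis genes 1 rose and 12 fell of 27 (1 and 12 adjusted over the list alone), with guaB at -1.54 and purH at -1.34. The nucleotide list had a median log2 change of -0.65 (camera adjusted p = 8.99e-05, 0.366 with an estimated correlation). Aminoacyl-tRNA synthetase genes fell in part (0 rose and 8 fell of 22 (0 and 11 adjusted over the list alone)), with pheS at -0.81 and pheT at -0.71. The synthetases had a median log2 change of -0.39 (camera adjusted p = 0.000192, 0.366 with an estimated correlation). Among translation factors 0 rose and 5 fell of 14 (0 and 5 adjusted over the list alone), with tsf at -0.92 and fusA at -0.87. Translation factors had a median log2 change of -0.27 (camera adjusted p = 0.01, 0.366 with an estimated correlation). For heat shock genes 3 rose and 7 fell of 20 (4 and 11 adjusted over the list alone), with hslU at -0.90 and dnaK at -0.74. The heat shock list had a median log2 change of -0.42 (camera adjusted p = 0.022, 0.541 with an estimated correlation). By limma under median-of-ratios scaling, rises and falls in the 12 lists that passed were 53 and 3 (CRP-linked), 0 and 47 (ribosomal proteins), 4 and 57 (amino acid), 2 and 14 (glycolysis), 11 and 0 (TCA) and 24 and 12 (NtrC/Nac), and 17 and 2 (RpoS), 0 and 5 (ammonium), 0 and 15 (nucleotide), 0 and 15 (synthetases), 0 and 6 (translation factors) and 2 and 14 (heat shock).

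The other 12 lists did not pass camera in the C-limitation, with adjusted p between 0.176 and 0.828. Among flagella and chemotaxis genes 4 rose and 0 fell of 53 (4 and 0 adjusted over the list alone), with the chemoreceptor gene trg at 3.87 and aer at 2.03 (median 0.86, adjusted p = 0.218). Among hibernation and rescue factors 4 rose and 1 fell of 8 (4 and 1 adjusted over the list alone), with the ribosome modulation factor gene rmf at 8806 ± 2482 ppm against 655 ± 142 ppm (median 0.60, adjusted p = 0.176). In the porin and lipoprotein list 1 rose and 3 fell of 10 (1 and 3 adjusted over the list alone), with ompX at -2.25 and ompF at 26884 ± 544 ppm against 8324 ± 344 ppm (median -0.29, adjusted p = 0.218). Respiration gave 9 rises and 4 falls in 30 genes (12 and 5 adjusted over the list alone), with nuoA at 1.32 and cydA at -1.29 (median 0.35, adjusted p = 0.589). Acetate metabolism gave 2 rises and 2 falls in 9 genes (2 and 2 adjusted over the list alone), with poxB at 1.57 and aceE at -1.24 (median -0.17, adjusted p = 0.58). Cold shock genes gave 1 rise and 1 fall in 11 genes (1 and 1 adjusted over the list alone), with cspG at -2.12 and cspE at 1.26 (median -0.19, adjusted p = 0.479). RNA degradation genes gave 1 rise and 0 falls in 16 genes (1 and 0 adjusted over the list alone) (median -0.22, adjusted p = 0.281). Iron acquisition genes gave 5 rises and 0 falls in 30 genes (1 and 0 adjusted over the list alone), with fhuE at 2.98 (median 0.33, adjusted p = 0.485). In 4 lists the sign of the median changed with the scaling. These were RNA polymerase and its regulators, where 4 rose and 1 fell of 19 (4 and 1 adjusted over the list alone) (median -0.03, adjusted p = 0.827), and nucleoid proteins, where 3 rose and 0 fell of 13 (3 and 0 adjusted over the list alone) (median 0.17, adjusted p = 0.789). The others were drug efflux, where 1 rose and 0 fell of 16 (0 and 0 adjusted over the list alone) (median 0.07, adjusted p = 0.827), and the SOS response, where 2 rose and 0 fell of 13 (1 and 0 adjusted over the list alone) (median 0.07, adjusted p = 0.789). Within the RNA polymerase list the anti-sigma factor gene rsd rose by 2.58 ± 0.18, rpoS by 2.13 ± 0.20 and rpoE by 1.86 ± 0.21, while rpoA fell by 1.07 on the log2 scale. With median-of-ratios scaling limma gave rises and falls of 4 and 0 (flagella), 3 and 1 (hibernation), 1 and 3 (porin), 4 and 6 (respiration), 1 and 3 (acetate) and 1 and 1 (cold shock), and 1 and 4 (RNA degradation), 1 and 2 (iron), 3 and 3 (RNA polymerase), 1 and 2 (nucleoid), 1 and 0 (efflux) and 2 and 3 (SOS).

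The comparison of a4 with the M9 wild type (n = 2 and 2) asked which transcripts changed when ammonium assimilation limited growth. Flagellar genes fell most. The flagellar rod and hook genes flgB (b1073), flgC, flgD, flgE, flgF and flgG changed by -7.22 ± 0.92, -7.12 ± 0.98, -6.96 ± 0.97, -6.70 ± 0.96, -6.51 ± 0.92 and -6.27 ± 0.93 on the log2 scale. The flagellin gene fliC (b1923) was at 194 ± 109 ppm against 15745 ± 3645 ppm (-6.44 ± 1.17, adjusted p = 0.000172), the flagellar sigma factor gene fliA changed by -6.56 ± 0.97, and fliF and fliG of the motor changed by -6.45 ± 0.95 and -6.31 ± 0.93. Among rises, rmf (b0953) was at 34735 ± 9550.0 ppm against 655 ± 142 ppm (5.72 ± 0.49, limma adjusted p = 4.89e-08). The acid chaperone gene hdeB (b3509) rose by 5.25 ± 0.43 and the porin gene ompC (b2215) by 5.19 ± 0.29, to 10494 ± 176 ppm against 287 ± 34.2 ppm. The other large rises were yebV (4.95 ± 0.23), ycaC (4.78 ± 0.21), yjfN (4.69 ± 0.24), the biofilm regulator gene bssR (4.52 ± 0.81), ydcH (4.51 ± 0.28), the ribosome-associated protein gene sra (4.50 ± 0.39) and yodD (4.47 ± 0.34). The titrated genes gltD and gltB changed by -2.71 ± 0.15 and -2.19 ± 0.25, and ptsG had a log2 change of -0.41 ± 0.37 (adjusted p = 0.344).

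In this comparison limma called 2045 of 3279 genes, 1739 higher and 306 lower, and 967 and 183 of them changed at least 2-fold. The median log2 change of all genes was 0.60. Median-of-ratios scaling moved it by -0.74 and gave 626 genes higher and 992 lower, so the share of changed genes that were higher was 85.0% as deposited and 38.7% after scaling. For 81.2% of genes the libraries did not overlap, where chance gives 33.3%. Medians of 16 of the 24 lists had another sign after that scaling, and of 17 with removal of the 10 most abundant genes counted too.

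The 7 lists that kept their sign under each scaling included the flagella and chemotaxis genes, of which 0 rose, 52 fell and 1 did not pass (0 and 52 adjusted over the list alone). The flagellar list as a group had a median of -5.56 (camera adjusted p = 2.37e-46, 0.11 with an estimated correlation). Of 54 ribosomal protein genes 0 rose, 46 fell and 8 did not pass (0 and 46 adjusted over the list alone), with rplB at -1.75, rplA at -1.72 and rplV at -1.69. Ribosomal proteins as a group had a median of -1.07 (camera adjusted p = 1.35e-38, 0.0216 with an estimated correlation). All 32 RpoS-associated stress genes rose (32 adjusted over the list alone), with hdeD at 4.68 and hdeA at 4.38. The RpoS list as a group had a median of 3.05 (camera adjusted p = 4.41e-11, 0.11 with an estimated correlation). The sigma factor gene rpoS (b2741) itself was at 1559 ± 69.4 ppm against 187 ± 19.5 ppm. Among purine and pyrimidine synthesis genes 3 rose and 17 fell of 27 (4 and 17 adjusted over the list alone), with purM at -2.88, purK at -2.85 and purL at -2.65. The nucleotide list as a group had a median of -1.44 (camera adjusted p = 2.08e-12, 0.11 with an estimated correlation). Among hibernation factors 6 rose and 0 fell of 8 (7 and 0 adjusted over the list alone), with elaB at 3.53 and yqjD at 1.69. Hibernation factors as a group had a median of 1.63 (camera adjusted p = 0.0464, 0.623 with an estimated correlation). Among ammonium assimilation genes 3 rose and 3 fell of 7 (3 and 3 adjusted over the list alone), 2 of the falls being gltB and gltD, which were titrated in this strain. The ammonium list as a group had a median of -0.25 (camera adjusted p = 0.00277, 0.11 with an estimated correlation). Without those genes it did not pass camera (adjusted p = 0.327, median 0.62 over 5 genes, gdhA included), a test added later. The glutamate dehydrogenase gene gdhA (b1761) was at 39.5 ± 3.78 ppm against 2004 ± 253 ppm (-5.63 ± 0.22), with strain not told apart from limitation. Translation factors gave 3 rises and 5 falls in 14 genes (3 and 5 adjusted over the list alone), with tufB at -1.67. Translation factors as a group had a median of -0.21 (camera adjusted p = 0.00279, 0.337 with an estimated correlation). The value of tufB is uncertain, since tufA is a near-identical copy. Scaled rises and falls by limma in these lists were 0 and 53 (flagella), 0 and 51 (ribosomal proteins), 28 and 0 (RpoS), 0 and 21 (nucleotide), 4 and 1 (hibernation), 0 and 4 (ammonium) and 1 and 9 (translation factors).

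Another 3 lists passed camera as lower than the other genes in the A-limitation although their medians were above 0. For amino acid biosynthesis 34 rose and 13 fell of 92 (34 and 13 adjusted over the list alone), with metE at -3.11 and aroF at -2.64, and the median of 0.23 became -0.54 under median-of-ratios scaling. Camera gave this list an adjusted p = 0.00937, 0.732 with an estimated correlation. Respiration gave 4 rises and 8 falls in 30 genes (4 and 6 adjusted over the list alone), with atpI at 1.39 and ndh at -1.15, and its median of 0.22 became -0.55. Camera gave this list an adjusted p = 0.003, 0.726 with an estimated correlation. Aminoacyl-tRNA synthetases gave 3 rises and 4 falls in 22 genes (2 and 2 adjusted over the list alone), with lysS at -0.71, and had a median of 0.01, a mean of -0.06 and a scaled median of -0.76. The scaled rises and falls by limma in these 3 lists were 7 and 46, 0 and 14 and 0 and 19. Camera gave this list an adjusted p = 0.00195, 0.623 with an estimated correlation.

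The other 14 lists did not pass in the A-limitation, with camera adjusted p between 0.195 and 0.998, and the medians of all of them changed sign under at least 1 scaling. CRP-linked carbon genes gave 35 rises and 8 falls in 69 genes (35 and 8 adjusted over the list alone), with the hexose phosphate transporter gene uhpT at -3.63 and treB at 3.22. NtrC/Nac genes gave 26 rises and 7 falls in 43 genes (28 and 7 adjusted over the list alone), with patA at 3.48 and astE at 2.21. Glycolysis gave 4 rises and 0 falls in 17 genes (3 and 0 adjusted over the list alone), with fbaB at 4.01. The TCA list gave 12 rises and 0 falls in 18 genes (14 and 0 adjusted over the list alone), with acnA at 1.74. Acetate metabolism gave 3 rises and 0 falls in 9 genes (3 and 0 adjusted over the list alone), with poxB at 3.31. Heat shock gave 8 rises and 2 falls in 20 genes (8 and 2 adjusted over the list alone), with ibpB at 2.31. Cold shock genes gave 6 rises and 0 falls in 11 genes (6 and 0 adjusted over the list alone), with cspI at 3.87. RNA degradation genes gave 3 rises and 0 falls in 16 genes (2 and 0 adjusted over the list alone), with rraA at 1.22. RNA polymerase and its regulators gave 11 rises and 2 falls in 19 genes (11 and 2 adjusted over the list alone), with rsd at 2.71 and rpoE at 1.75. Nucleoid proteins gave 4 rises and 0 falls in 13 genes (3 and 0 adjusted over the list alone), with dps at 2.36. Porins gave 3 rises and 2 falls in 10 genes (2 and 2 adjusted over the list alone), with nmpC at -3.46 and ompW at 2.77. Drug efflux genes gave 10 rises and 0 falls in 16 genes (10 and 0 adjusted over the list alone), with emrE at 1.45. The SOS list gave 6 rises and 0 falls in 13 genes (6 and 0 adjusted over the list alone), with umuD at 2.01. Iron genes gave 12 rises and 1 fall in 30 genes (9 and 1 adjusted over the list alone), with fiu at -2.09. Under median-of-ratios scaling the rises and falls by limma in these lists were 18 and 20 (CRP-linked), 16 and 15 (NtrC/Nac), 2 and 6 (glycolysis), 1 and 3 (TCA), 1 and 3 (acetate), 3 and 12 (heat shock) and 3 and 4 (cold shock). In the others they were 0 and 9 (RNA degradation), 3 and 6 (RNA polymerase), 1 and 6 (nucleoid), 2 and 5 (porin), 1 and 3 (efflux), 2 and 5 (SOS) and 0 and 5 (iron). The RNA polymerase subunit genes rpoB and rpoC had log2 changes of -0.06 ± 0.20 and -0.10 ± 0.16 (limma adjusted p = 0.798 and 0.592), and the RNase E gene rne one of -0.09 ± 0.20 (adjusted p = 0.715).

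How transcripts changed when translation was inhibited was asked by comparing r4, with 8 µM chloramphenicol, with the wild type in MOPS medium (n = 2 and 2). The ribosomal protein gene rplO (b3301) was at 15757 ± 2657 ppm against 3937 ± 1298 ppm (log2 change 2.03 ± 0.22, limma adjusted p = 5.02e-06). The phage shock genes pspD (b1307), pspC and pspB rose by 3.23 ± 0.49, 2.44 ± 0.31 and 2.43 ± 0.29 (adjusted p = 8.41e-05 for pspD). Other large rises were gfcA (2.70 ± 0.31), the formaldehyde repressor gene frmR (2.45 ± 0.51), the toxin gene ortT (2.33 ± 0.39), the manganese exporter gene mntP (2.23 ± 0.29), the betaine repressor gene betI (2.04 ± 0.18) and the ribosome rescue gene arfA (2.03 ± 0.55). The flagellin gene fliC was at 1087 ± 1442 ppm against 21959.5 ± 370.5 ppm (-5.85 ± 1.17), with 1 r4 library far above the other. Falls also covered nirB (-5.78 ± 1.06), the radical cofactor gene grcA (-5.70 ± 0.63), bssR (-5.41 ± 0.81), malE (-5.27 ± 0.26) and malK (-5.27 ± 0.37). The chemoreceptor genes tar and tsr fell by 5.06 and by 5.04 on the log2 scale, the chemotaxis regulator gene cheY by 4.80 and the ribosome-associated inhibitor gene raiA by 4.79.

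With limma, 1472 of 3279 genes changed, 455 higher and 1017 lower, and 172 and 534 changed at least 2-fold. The median log2 change was -0.18. Under median-of-ratios scaling 580 were higher and 960 lower. With ribosomal protein and flagellar genes removed and the rest rescaled, the split turned to 1003 higher and 590 lower and the median to 0.16, so which direction prevailed depended on the scaling. The r4 cultures grew at 0.4 and 0.28 per h, and without replicate 2 of r4 the count was 926. Libraries of the groups did not overlap for 74.1% of genes, where chance gives 33.3%.

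Ribosomal protein genes rose, with rplF at 1.88, rplE at 1.85 and rpmD at 1.78, and of the 54 30 rose, 0 fell and 24 did not pass (30 and 0 adjusted over the list alone). Ribosomal proteins showed a median of 0.52 (camera adjusted p = 5.7e-14, 0.487 with an estimated correlation). Of the flagella and chemotaxis genes 0 rose and 51 fell of 53 (0 and 51 adjusted over the list alone). The flagellar list showed a median of -4.19 (camera adjusted p = 8.29e-11, 0.487 with an estimated correlation). Their summed share was 0.830% and 0.0811% in replicates 1 and 2 of r4, against 5.21% and 4.72% in MOPS, so the size of the fall rests mostly on replicate 2. In the CRP-linked carbon list 6 rose and 44 fell of 69 (6 and 44 adjusted over the list alone), with malP at -3.85 and lamB at -3.59. The CRP-linked list showed a median of -0.86 (camera adjusted p = 8.02e-06, 0.487 with an estimated correlation). Glycolysis fell (0 rose and 15 fell of 17 (0 and 15 adjusted over the list alone)), with tpiA at -2.48 and fbaA at -2.11. The glycolysis list showed a median of -1.42 (camera adjusted p = 1.74e-05, 0.487 with an estimated correlation). In the TCA list 0 rose and 13 fell of 18 (0 and 14 adjusted over the list alone), with sucA at -2.21, sucD at -2.16 and sucC at -2.14. The TCA list showed a median of -1.33 (camera adjusted p = 2.22e-05, 0.487 with an estimated correlation). In the acetate list 0 rose and 6 fell of 9 (0 and 6 adjusted over the list alone), with pflB at -2.13. The acetate list showed a median of -0.79 (camera adjusted p = 0.0339, 0.487 with an estimated correlation). Iron acquisition gave 0 rises and 20 falls in 30 genes (0 and 22 adjusted over the list alone), with fes at -2.45 and fecI at -2.06. The iron list showed a median of -1.09 (camera adjusted p = 0.000114, 0.495 with an estimated correlation). Amino acid biosynthesis gave 8 rises and 45 falls in 92 genes (8 and 49 adjusted over the list alone), with hisG at -3.12 and ilvC at -2.84. Amino acid genes showed a median of -0.58 (camera adjusted p = 0.00366, 0.495 with an estimated correlation). RpoS-associated genes gave 1 rise and 21 falls in 32 genes (2 and 21 adjusted over the list alone), with osmE at -2.06 and dps at -1.96. The RpoS list showed a median of -0.98 (camera adjusted p = 0.00216, 0.487 with an estimated correlation). The gene rpoS itself rose by 0.61 ± 0.20. NtrC/Nac genes gave 2 rises and 18 falls in 43 genes (2 and 18 adjusted over the list alone), with gltI at -2.72. The NtrC/Nac list showed a median of -0.38 (camera adjusted p = 0.0104, 0.487 with an estimated correlation).

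The remaining 14 lists did not pass in the R-limitation, with camera adjusted p between 0.0536 and 0.967. Hibernation factors gave 2 rises and 6 falls in 8 genes (2 and 6 adjusted over the list alone), with elaB at -2.06 and rmf at -1.73. Ammonium assimilation gave 0 rises and 3 falls in 7 genes (0 and 3 adjusted over the list alone), with gdhA at -1.52. Translation factors gave 3 rises and 0 falls in 14 genes (2 and 0 adjusted over the list alone), with tsf at 0.93. Synthetases gave 0 rises and 4 falls in 22 genes (0 and 3 adjusted over the list alone), with serS at -1.48. Cold shock genes gave 5 rises and 1 fall in 11 genes (5 and 1 adjusted over the list alone), with cspE at -2.97, cspG at 1.97 and cspA at 1.30. Purine and pyrimidine synthesis gave 3 rises and 9 falls in 27 genes (3 and 9 adjusted over the list alone), with pyrI at -1.77 and pyrF at 1.55, and its median was 0.03 and its mean -0.28. RNA polymerase genes gave 6 rises and 7 falls in 19 genes (8 and 7 adjusted over the list alone), with rpoA at 1.07, rho at 1.04 and fliA at -4.68. Nucleoid proteins gave 2 rises and 3 falls in 13 genes (2 and 3 adjusted over the list alone), with stpA at -2.22 and hns at 0.97. Heat shock gave 0 rises and 5 falls in 20 genes (0 and 4 adjusted over the list alone), with groS at -1.40. Respiratory genes gave 1 rise and 10 falls in 30 genes (0 and 10 adjusted over the list alone). Porins gave 0 rises and 5 falls in 10 genes (0 and 5 adjusted over the list alone), with nmpC at -4.03. The SOS list gave 0 rises and 6 falls in 13 genes (0 and 6 adjusted over the list alone), with sulA at -1.17. RNA degradation (1 rose and 6 fell of 16 (1 and 6 adjusted over the list alone), median -0.08, with orn at -1.46) and drug efflux (3 rose and 5 fell of 16 (3 and 5 adjusted over the list alone), median -0.05, with soxS at -1.62) changed the sign of their medians with the scaling.

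**Figure D2:**
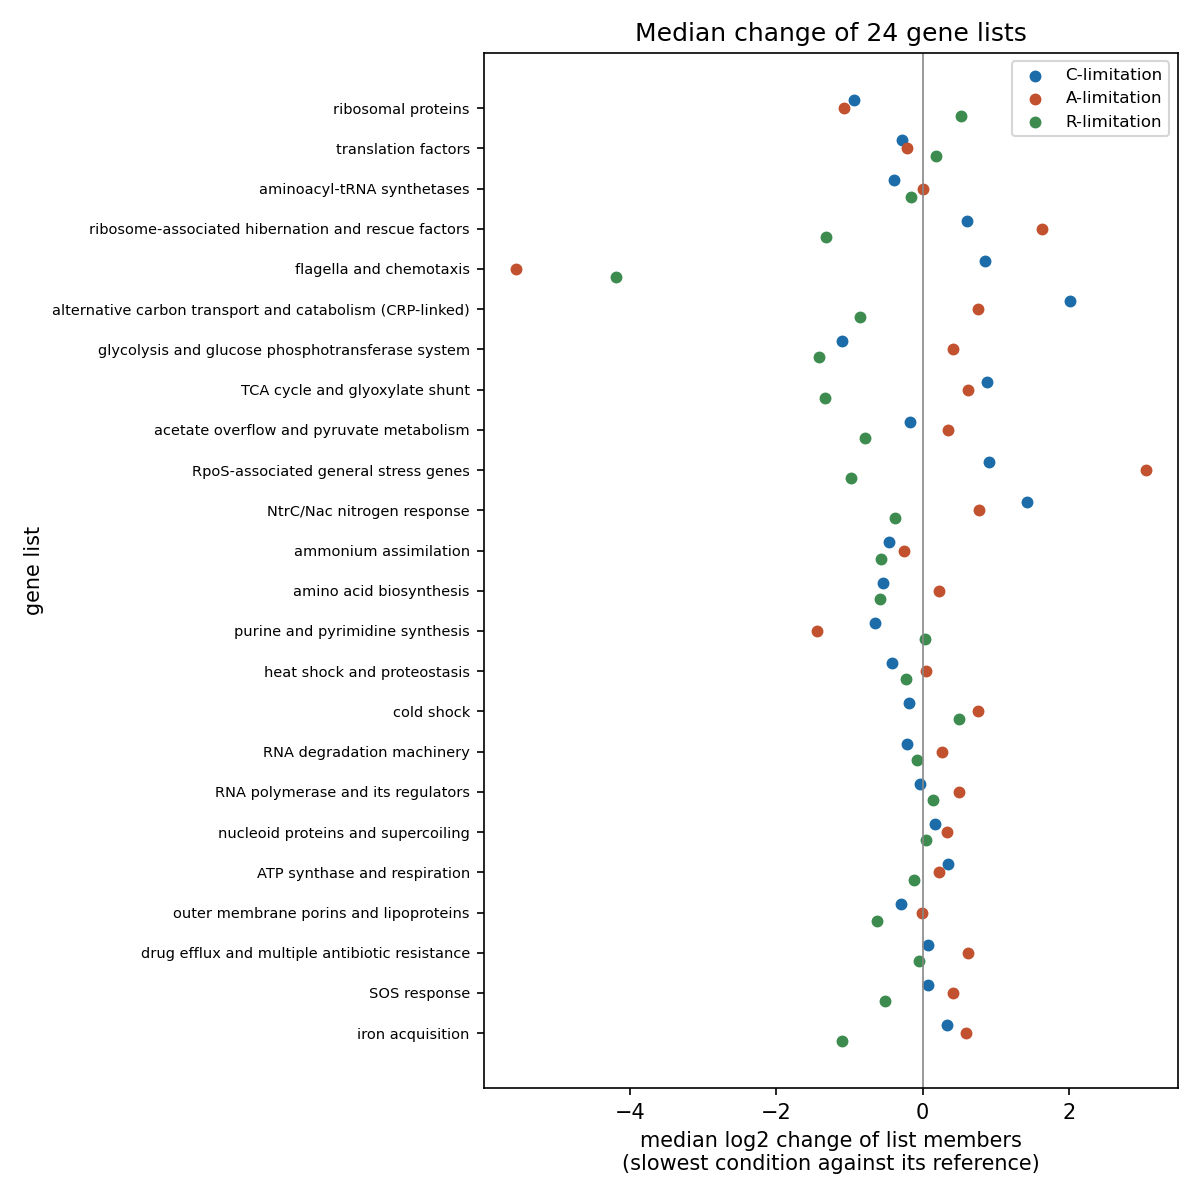
Median log2 change of the members of 24 gene lists (x axis) in the slowest replicated condition of each limitation against its reference, 1 point per list and limitation. Flagella and chemotaxis lie at -5.56 in the A-limitation and 0.86 in the C-limitation, and under the scalings tried the medians of 4 lists in the C-limitation, 17 in the A-limitation and 2 in the R-limitation had another sign.

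Over the 3 limitations, 72 list tests were made, of which 32 passed camera with the preset correlation and 1, the ribosomal proteins in the A-limitation, passed with an estimated correlation. With fry, which asks whether a list moves one way without comparing it with other genes, 51 passed.

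Because the A- and C-limitation used M9 medium and the R-limitation MOPS medium, the wild type in both media was compared (n = 2 and 2). The potassium transporter gene kdpA (b0698) was at 336 ± 80.6 ppm against 0.784 ± 0.0716 ppm in MOPS against M9 (log2 change 7.54 ± 0.40, limma adjusted p = 2.36e-10), and kdpB rose by 6.34 ± 0.30. The thiamine synthesis genes thiH, thiF, thiE, thiG, thiS and thiC rose by 6.11, 5.89, 5.86, 5.80, 5.75 and 5.57, and the lipopolysaccharide genes ais and arnB by 6.79 and 5.50. The metal efflux genes cusF, cusB and cusA fell by 2.25, by 2.14 and by 1.88, and the siderophore synthesis genes entH, entB and entA changed by -1.89, -1.83 and -1.68. The regulator gene yrbL (-2.69), nrdF of ribonucleotide reductase (-1.89), metF (-1.66) and trpD (-1.61) were also lower in MOPS. In the amino acid list 1 rose and 24 fell of 92 (4 and 31 adjusted over the list alone). Amino acid genes had a median in MOPS of -0.25 (camera adjusted p = 8.26e-11, 0.518 with an estimated correlation). Among ribosomal proteins 2 rose and 13 fell of 54 (5 and 20 adjusted over the list alone). Ribosomal proteins had a median in MOPS of -0.30 (camera adjusted p = 6.67e-07, 0.703 with an estimated correlation). For RpoS-associated genes 8 rose and 1 fell of 32 (14 and 2 adjusted over the list alone). The RpoS list had a median in MOPS of 0.54 (camera adjusted p = 0.00402, 0.932 with an estimated correlation). For iron acquisition 0 rose and 2 fell of 30 (0 and 2 adjusted over the list alone). The iron list had a median in MOPS of -0.32 (camera adjusted p = 0.00144, 0.932 with an estimated correlation). For ammonium assimilation 0 rose and 2 fell of 7 (1 and 4 adjusted over the list alone). The ammonium list had a median in MOPS of -0.43 (camera adjusted p = 0.00402, 0.45 with an estimated correlation). The NtrC/Nac list gave 2 rises and 9 falls in 43 genes (4 and 15 adjusted over the list alone) with a mean of -0.17 and a median of -0.12 after median-of-ratios scaling. The NtrC/Nac list had a median in MOPS of 0.00 (camera adjusted p = 0.00402, 0.703 with an estimated correlation). In the synthetase list 1 rose and 0 fell of 22 (1 and 0 adjusted over the list alone). The synthetases had a median in MOPS of -0.14 (camera adjusted p = 0.0344, 0.932 with an estimated correlation). No heat shock gene passed limma and 2 fell at an unadjusted p under 0.05. The heat shock list had a median in MOPS of -0.17 (camera adjusted p = 0.0344, 0.932 with an estimated correlation). Scaled rises and falls by limma in these lists were 1 and 30 (amino acid), 0 and 18 (ribosomal proteins), 8 and 2 (RpoS), 0 and 2 (iron), 0 and 4 (ammonium), 2 and 13 (NtrC/Nac), 0 and 0 (synthetases) and 0 and 2 (heat shock).

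In this comparison 347 genes changed by limma, 250 higher and 97 lower, and 124 and 42 changed at least 2-fold, with a median of 0.12 over all genes. Median-of-ratios scaling moved the median by -0.13 and gave 190 higher and 185 lower, 50.7% against 72.0% higher as deposited. Without replicate 2 of MOPS 131 genes were called, without replicate 1 of M9 147, and with a term for the sequencing set 532. Groups did not overlap for 51.5% of genes, where chance gives 33.3%, and the first libraries of both media came from different lanes.

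The slowest cultures of the C- and A-limitation were compared directly to ask how the limitations differ at similar growth rates (n = 2 and 2). In c4 against a4, lamB was higher by 8.11 ± 0.37, the flagellin gene fliC was at 37430.2 ± 112 ppm against 194 ± 109 ppm (7.71 ± 1.17), and fliA, flgC, flgD, flgB and flgE were higher by 7.93, 7.73, 7.71, 7.68 and 7.68. The chemoreceptor gene tar was higher by 7.38 ± 1.05. Lower in c4 were nirB (-6.32 ± 1.06), the nitrate reductase gene narG (-6.31 ± 1.18), ynfM (-5.97 ± 0.29), the nitrate transporter gene narK (-5.63 ± 1.45), ptsG (-5.38 ± 0.37), nirD (-5.10 ± 0.95), bssR (-4.93 ± 0.81), mqo (-4.80 ± 0.37), hdeB (-4.80 ± 0.43) and glnK (-4.77 ± 0.41). Between these unlike strains gdhA was higher in c4 by 5.17 ± 0.22, and thrA, thrB and thrC of threonine synthesis were lower (-3.02, -2.95 and -2.73). Of 3279 genes, limma called 2079, 470 higher and 1609 lower in c4, 311 and 788 at least 2-fold, with a median of -0.52. Median-of-ratios scaling moved the median by 0.56 and gave 887 higher and 678 lower, 56.7% against 22.6% higher as deposited. The groups did not overlap for 85.3% of genes, where chance gives 33.3%.

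Of the lists in this comparison, flagella and chemotaxis gave 53 rises and 0 falls in 53 genes (53 and 0 adjusted over the list alone). The flagellar list together had a median of 6.34 (camera adjusted p = 1.4e-36, 0.329 with an estimated correlation). For CRP-linked carbon 43 rose and 7 fell of 69 (43 and 7 adjusted over the list alone). The CRP-linked list together had a median of 1.23 (camera adjusted p = 2.12e-21, 0.101 with an estimated correlation). RpoS-associated genes gave 0 rises and 29 falls in 32 genes (0 and 30 adjusted over the list alone). The RpoS list together had a median of -1.82 (camera adjusted p = 1.09e-06, 0.406 with an estimated correlation). Glycolysis gave 0 rises and 15 falls in 17 genes (0 and 16 adjusted over the list alone). The glycolysis list together had a median of -1.47 (camera adjusted p = 0.000671, 0.671 with an estimated correlation). Purine and pyrimidine synthesis gave 15 rises and 6 falls in 27 genes (15 and 7 adjusted over the list alone). The nucleotide list together had a median of 0.60 (camera adjusted p = 0.000742, 0.671 with an estimated correlation). NtrC/Nac genes gave 20 rises and 11 falls in 43 genes (20 and 11 adjusted over the list alone). The NtrC/Nac list together had a median of 0.41 (camera adjusted p = 4.17e-05, 0.329 with an estimated correlation). Ribosomal proteins gave 9 rises and 1 fall in 54 genes (0 and 0 adjusted over the list alone). Ribosomal proteins together had a median of 0.24 (camera adjusted p = 4.34e-05, 0.671 with an estimated correlation). In the TCA list 7 rose and 1 fell of 18 (7 and 1 adjusted over the list alone). The TCA list together had a median of 0.17 (camera adjusted p = 3.58e-05, 0.667 with an estimated correlation). Respiration gave 11 rises and 6 falls in 30 genes (11 and 6 adjusted over the list alone). The respiration list together had a median of 0.35 (camera adjusted p = 0.000742, 0.763 with an estimated correlation). Under median-of-ratios scaling the rises and falls by limma were 53 and 0 (flagella), 51 and 3 (CRP-linked), 1 and 25 (RpoS), 1 and 13 (glycolysis), 17 and 2 (purine and pyrimidine), 24 and 8 (NtrC/Nac), 43 and 0 (ribosomal proteins), 12 and 0 (TCA) and 19 and 3 (respiration).

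Genes that changed in more than 1 limitation were counted. In both the C- and the A-limitation 610 genes were higher, where independent calls would give 429.6, and 137 were lower, against 45.3. Another 27 genes were higher in the C- and lower in the A-limitation, and 120 the reverse, against 75.6 and 257 for independent calls. Across genes, which are not independent replicates, the changes of both limitations correlated with r = 0.260 (covariance 0.370, 61.1% with the same sign). In 100 simulations of unchanged groups that shared the M9 libraries, the mean r was 0.501, the covariance 0.0434 and 66.7% of genes had the same sign, so part of the overlap may come from the shared controls. The measured covariance exceeded the simulated one by 0.327. With the MOPS cultures as the reference of the A-limitation r was 0.188, and with them as the reference of the C-limitation 0.0874. Without shared libraries, 285 genes were higher in the C- and lower in the R-limitation (251 for independent calls), 85 the reverse (67.3), 81 were higher in both (112) and 175 lower in both (150.4), with r = -0.123 across genes. For the A- and R-limitation 503 genes were higher in the first and lower in the second (539 for independent calls), 59 the reverse (42.5), 238 were higher in both (241) and 128 lower in both (94.9), with r = 0.266 and 44.6% of genes with the same sign.

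Whether the response to chloramphenicol differed from the nutrient limitations was tested as a difference of changes, each against its own medium. The change differed for 1490 genes between the R- and C-limitation and for 1941 between the R- and A-limitation by limma. Among ribosomal proteins 48 of 54 had a higher change in the R- than in the C-limitation (51 adjusted over the list alone, median log2 change 1.44, camera adjusted p = 6.09e-27, 0.0824 with an estimated correlation). The same count of 48 held against the A-limitation (49 adjusted over the list alone, median log2 change 1.56, camera adjusted p = 1.93e-49, 0.00715 with an estimated correlation). All 53 flagella and chemotaxis genes had a lower change in the R- than in the C-limitation (53 adjusted over the list alone, camera adjusted p = 2.12e-07, 0.755 with an estimated correlation). Against the A-limitation 0 of the 53 passed limma and 0 had an unadjusted p under 0.05. The median difference of that list was 1.39 (camera adjusted p = 3.04e-11, 0.543 with an estimated correlation).

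Growth-rate slopes were sought within each limitation. In the C- and A-limitation strain changes with growth rate and may explain part of these slopes and of the shares below. In the C-limitation 1424 of 3167 genes had a slope by limma (n = 10 libraries), 524 positive and 900 negative. In the A-limitation 1920 of 3317 had one (n = 9), 275 positive and 1645 negative, and in the R-limitation 2023 of 3106 (n = 11), 1279 positive and 744 negative. Under median-of-ratios scaling the positive and negative slopes numbered 868 and 696 in the C-limitation, 1001 and 688 in the A-limitation and 1176 and 875 in the R-limitation. Of 2963 genes tested in all 3 fits, 100 had a negative slope in each limitation and 41 a positive slope, where independent calls would give 75.2 and 20.5. Given the overlap of the C- and A-limitation, which share the M9 libraries, an independent R-limitation would give 110.7 and 55.8. Slopes of unlike sign were called for 363 genes.

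The summed share of ribosomal protein transcripts was 33.7 ± 1.64% in M9, 18.6 ± 2.28% in c4, 17.1 ± 0.663% in a4, 29.5 ± 3.76% in MOPS and 48.2 ± 2.51% in r4. It rose with growth rate in the C-limitation (r = 0.959, permutation p = 1e-05, adjusted p = 5.54e-05, rho = 0.964 with permutation p = 4e-05, n = 10, r = 0.961 without the 2 farthest) and in the A-limitation (r = 0.957, exact permutation p = 0.000353, adjusted p = 0.00102, rho = 0.933 with exact permutation p = 0.00075, n = 9, r = 0.923 without the 2 farthest), and fell with growth rate in the R-limitation (r = -0.962, permutation p = 2e-05, adjusted p = 9e-05, rho = -0.900 with permutation p = 0.00049, n = 11, r = -0.948 without the 2 farthest). For the C-limitation the p of 1e-05 is the smallest the permutations can give. Within the first set of the R-limitation r was -0.985 (n = 6), and the sets of the other limitations held 5 libraries or fewer. The flagellar share was 4.48 ± 0.129% in M9, 9.10 ± 0.255% in c4 and 0.455 ± 0.529% in r4. In the A-limitation it was 2.60 ± 0.291% in a1 and 0.0839 ± 0.00522%, 0.0727% and 0.104 ± 0.0232% in a2, a3 and a4. Because those libraries form a pair of separate clusters, no correlation is given for them. The CRP-linked share rose from 0.553 ± 0.0406% to 5.56 ± 0.191% (r = -0.952, permutation p = 4e-05, adjusted p = 0.000169, rho = -0.903 with permutation p = 0.0009, n = 10, r = -0.923 without the 2 farthest), and the hibernation share from 0.424 ± 0.0351% to 4.42 ± 0.874% in a4. Of 72 relations between a list share and growth rate, 47 passed by permutation tests with Benjamini-Hochberg adjustment and 35 without the 2 libraries farthest from the median growth rate. The relation of the TCA list in the C-limitation rested on those libraries (r = -0.742, and -0.178 without them).

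**Figure D3:**
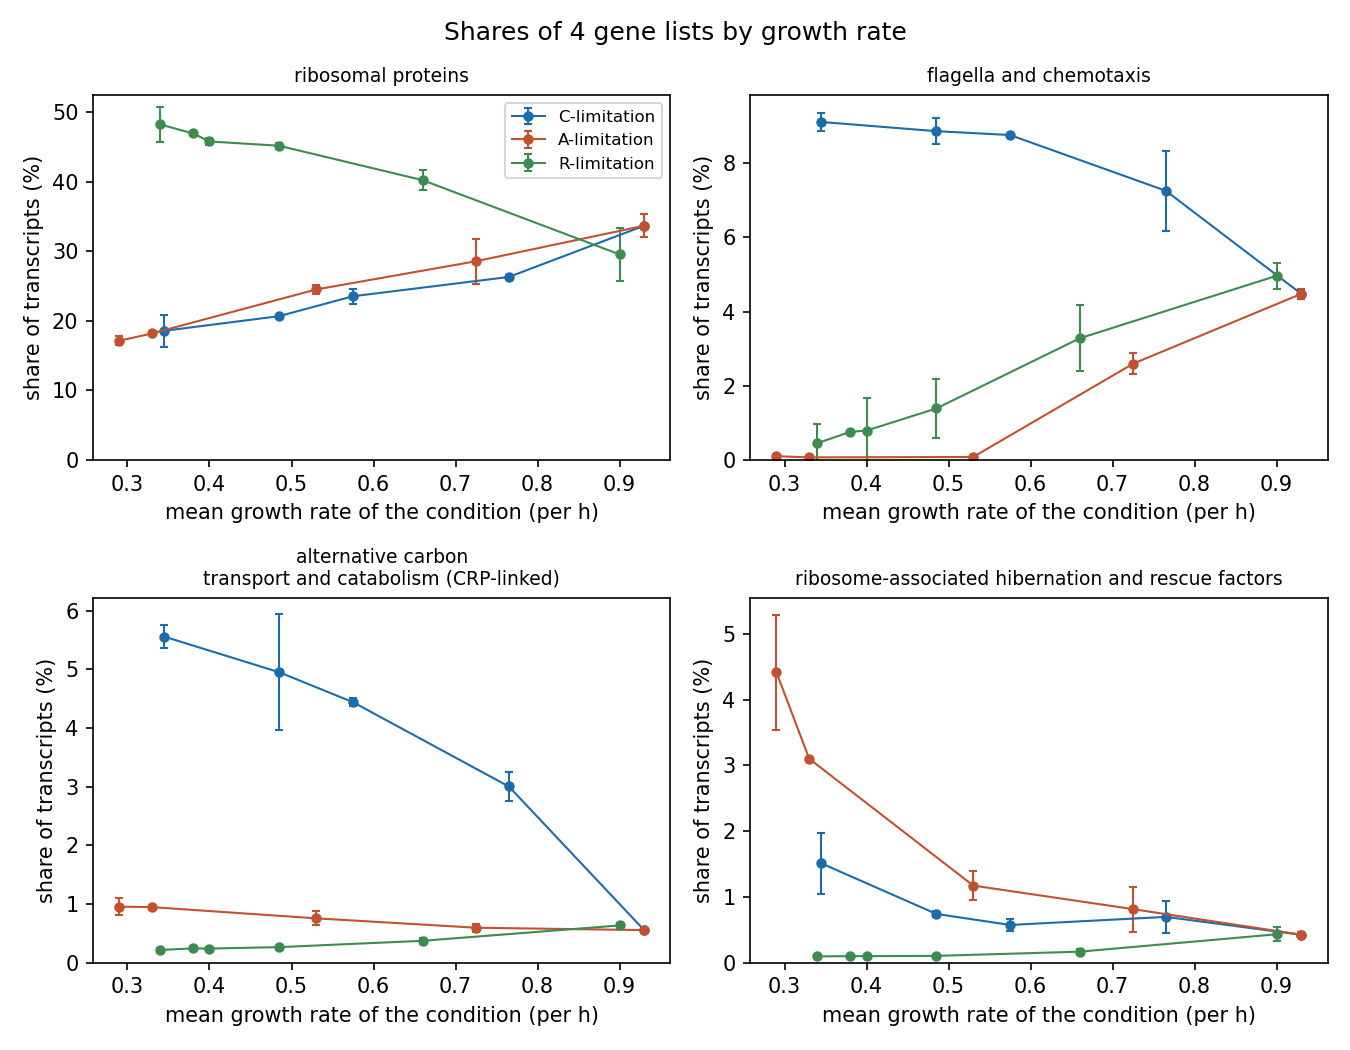
Share of transcripts (%) of 4 gene lists against the mean growth rate of the condition (per h), with points for condition means and bars for SD over 2 libraries (a3 and r5 have 1 library and no bar). The ribosomal protein share was 33.7% in M9 and 18.6% in c4, and was 29.5% in MOPS and 48.2% in r4.

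To ask how stable transcripts were, the authors added rifampicin, which blocks transcription initiation, and took 1 library at each of 0, 1, 2, 3, 5, 7, 9 and 11 min from a wild-type culture (the reference course) and a C-limited culture. Since each library sums to the same total, slopes are changes in the share of the remaining pool in log2 units per min, and no value has a replicate. In the reference course the flagellar genes flgJ (b1081), fliJ, fliK and flgH had slopes of -0.67 ± 0.12, -0.66 ± 0.14, -0.66 ± 0.12 and -0.61 ± 0.09 (± SE). Also steep were cysM (-0.65 ± 0.11), sdhD (-0.64 ± 0.11), entH (-0.64 ± 0.10), rbsK (-0.64 ± 0.10), nuoE (-0.61 ± 0.06) and murF (-0.61 ± 0.11). Except for sdhD, these and the flagellar genes above were higher at 2 than at 0 min, so their slopes do not rank decay. Slopes above 0 were largest for the toxin gene ldrD (b4453) (0.43 ± 0.03), yjbE (0.41 ± 0.04) and the major outer membrane lipoprotein gene lpp (b1677) (0.40 ± 0.03). The gene lpp went from 26369.8 ppm at 0 min to 398155 ppm at 11 min in the reference course and from 14369 to 181488 ppm in the C-limited course. Next came sgrT (0.39), rmf (0.38), tisB (0.38), speE (0.36), gnd (0.34), grxB (0.34) and uhpT (0.34). The level of ldrD is uncertain because of its close copies, and that of sgrT because it overlaps a small RNA.

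Of 2744 genes, limma gave a slope other than 0 to 2101 in the reference course, 197 rising and 1904 falling, and to 1707 in the C-limited course, 114 rising and 1593 falling. Under median-of-ratios scaling 433 rose and 529 fell in the reference course and 154 rose and 13 fell in the C-limited one. The RNase E gene rne had a slope of -0.50 ± 0.10 in the reference course and the RNA polymerase genes rpoB, rpoC and rpoD had -0.33 ± 0.05, -0.14 ± 0.09 and -0.13 ± 0.06 (limma adjusted p = 6.24e-05, 0.152 and 0.0748). For rpoS and rsd slopes were -0.30 ± 0.06 and -0.35 ± 0.07. Across genes, which are not independent replicates, the slopes of both courses correlated with r = 0.824 and the slope in the reference course correlated with abundance in the M9 steady state with r = -0.261. In the C-limited course that correlation, with abundance in c4, was -0.150, and over the time points 0 to 5 min and 0 to 3 min of the reference course it was -0.0116 and 0.110, so its sign depended on the time points used. Levels at 0 min correlated with the steady state with r = 0.969 (reference course with M9) and 0.960 (C-limited course with c4).

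**Figure D4:**
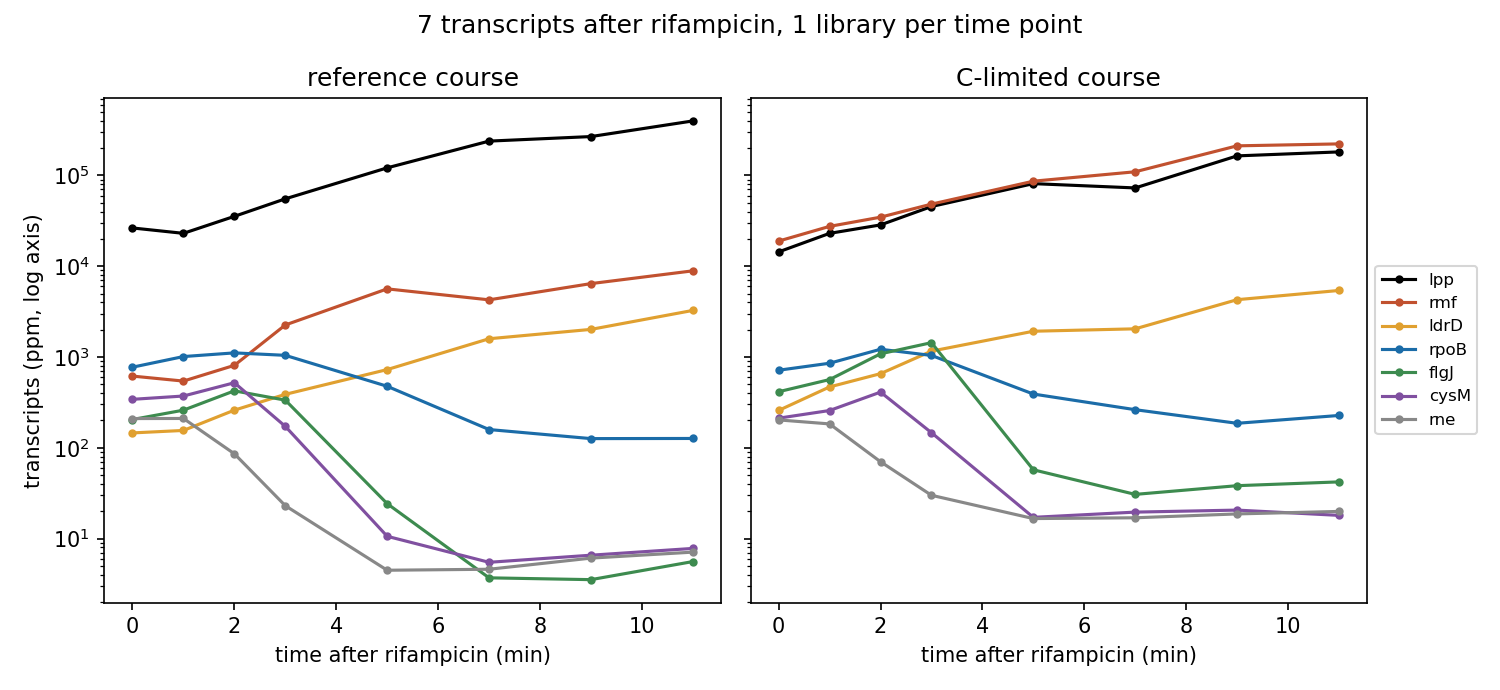
Levels of 7 transcripts (ppm, log axis) against time after rifampicin (min) in the reference and C-limited courses, 1 library per point and no error bars. The gene lpp rose to 398155 ppm at 11 min in the reference course, and flgJ was higher at 2 min than at 0 min before it fell.

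Ribosomal protein transcripts mostly fell in share, with 44 of 54 falling and 2 rising in the reference course and 49 and 0 in the C-limited course (median slopes -0.30 and -0.21, camera adjusted p = 0.00227 and 0.000157, adjusted p = 0.598 and 0.493 with an estimated correlation). Of the RpoS-associated genes 8 fell and 10 rose in the reference course (camera adjusted p = 9.9e-08, 0.0641 with an estimated correlation), and in the C-limited course the estimated-correlation adjusted p was 0.0422. Of the amino acid biosynthesis genes 83 fell and 3 rose (median -0.40), and of the flagellar genes 42 fell and 1 rose (median -0.45). Of the hibernation factors 5 rose and 0 fell of 8 in the reference course by limma (camera adjusted p = 3.03e-07, 0.0641 with an estimated correlation). In the C-limited course 3 of them rose and 1 fell, with a median of -0.04 (camera adjusted p = 0.000215, 0.161 with an estimated correlation). Of 10 porin and lipoprotein genes 4 rose and 3 fell in the reference course.

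The courses were compared to ask whether stability differed under C-limitation. The carbamoyl phosphate synthetase genes carA (b0032) and carB rose in share in the reference course (0.25 ± 0.06 and 0.18 ± 0.04) and fell in the C-limited course (-0.24 ± 0.06 and -0.27 ± 0.04), with limma adjusted p = 0.00648 and 0.000411 for the difference. Differences in the same direction were seen for zntR (-0.44 ± 0.10), the hibernation factor gene hpf (-0.41 ± 0.07) and yqgB (-0.38 ± 0.05), and for speE (-0.24 ± 0.04). The dihydroxyacetone kinase genes dhaL, dhaK and dhaM fell in the reference course (-0.36, -0.28 and -0.45) and had slopes of 0.10, 0.17 and 0.00 in the C-limited one. The siderophore receptor gene fepA and the galactose transporter gene mglC differed by 0.36 ± 0.07 and 0.35 ± 0.08. In all, 70 genes differed by limma, 51 with a lower and 19 with a higher slope in the C-limited course, and 333 had an unadjusted p under 0.05. Under median-of-ratios scaling 6 genes differed, 0 with a higher and 6 with a lower slope, 2 of them among the 70, and with the time points 0 to 3 min 0 genes by limma (355 unadjusted). Leaving out 1 time point gave 23 genes without 0 min, 18 without 1 min, 22 without 2 min, 26 without 3 min, 66 without 5 min, 43 without 7 min, 13 without 9 min and 85 without 11 min. With 1 library per time point, this comparison has no replicate of either course.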

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

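All tests of explanations in this part were chosen only after the results they address had been seen, and their thresholds were set knowing most of the values.

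Differences between groups marked 4 results for a closer look. The direct comparison of c4 with a4 called 2079 genes by limma, 470 higher and 1609 lower in c4, led by lamB (log2 8.11), fliA (7.93) and nirB (-6.32). The change in the R-limitation differed from that in the C-limitation for 1490 genes and from that in the A-limitation for 1941, each tested as a difference of changes. Ribosomal protein genes had a median difference of 1.44 and 1.56 in these tests. The decay slope differed between the rifampicin courses for 70 genes, among them carA, carB and dhaM. When course labels were exchanged within time points, 9 of 100 exchanges drawn gave at least as many genes, the real one included, and the highest other gave 737. Since the courses differ in level, an exchange turns levels into slopes, so this count does not bear on chance. In a test added for that reason, the mean of each course was removed per gene. Then 2 of 100 exchanges gave as many genes, the real one included, and the highest other gave 70. An exchanged labelling reached the real count and no time point is replicated, so chance is not excluded for it. With 1 culture per course, a difference between cultures cannot be told from an effect of the limitation.

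Flagella and chemotaxis genes fell in a4 (52 of 53, median log2 change -5.56) and had a median of 0.86 in c4. In a1, the fastest culture of the same strain, their median against M9 was -0.98 (5th to 95th percentile -1.27 to -0.34). This argues against the strain background as the whole cause, but not as a part. Median-of-ratios scaling left the median at -6.24, so scaling does not explain it. Within each set by title their share fell at least 37.8-fold, but lanes were not tested. Within the strain, 52 genes fell from a1 to a4 (median -4.70). A low level of gltB alone is not enough for the fall, since c4 had 293 ± 32.95 ppm and a2 518 ± 93.9 ppm, with flagellar shares of 9.10 ± 0.255% and 0.0839 ± 0.00522%. In r4, where gltBD was not titrated, 51 of the 53 genes also fell (median -4.19), with shares of 0.830% and 0.0811% in its replicates. The cause stays open, as IPTG dose and growth rate change together in the A-limitation.

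Most of the changed genes in a4 were higher than in M9 (1739 of 2045). Without the 10 most abundant genes 85.3% were still higher, which argues against a few abundant genes as the cause. Genes at 20 to 50 ppm gained a median of 16.2 ppm and those at 1 to 2 ppm 1.52 ppm, a ratio of 10.6. An even background alone would give like gains, but one beside a proportional rise is not excluded. With ribosomal protein and flagellar genes removed and the rest rescaled, the median change of the other genes was 0.22 in place of 0.63, and 1158 rose and 423 fell. Loss of those transcripts from a fixed sum may thus account for part of the rise. Fractions carry no absolute scale, so whether the rest is a change per cell stays open.

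Shares that fell early after rifampicin stopped falling late, though decay may have gone on. Choosing genes partly on 5 min levels favours such a turn. In 1419 genes of the reference course and 1482 of the C-limited course the median log2 change was -4.20 and -3.62 from 0 to 5 min, and 0.43 and 0.55 from 5 to 11 min. Levels at 11 min still followed those at 0 min of the same course with rank correlations of 0.786 and 0.898, which argues against an even background. The other course's level at 0 min had a coefficient of at most 0.0379 ± 0.0197 (SE) beside 0.854 and 0.912 for the own course, which argues against reads carried over between courses. No biological explanation was tested, and what keeps a median of 4.91% and 10.2% of the starting share at 11 min stays open.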

How the results depend on the processing

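The block for the list tests, the lists without titrated genes, the single-condition replacements by c3, a2 and r3, the omission of a1 or r4 from the slopes, the time points 0 to 3 min and the omission of single time points from correlations were chosen only after the data were seen, and the other alternatives were planned.

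For c4 against M9, 1295 genes became 731 with c1 as the reference and otherwise stayed between 904 and 1614. For a4 against M9 counts were 1469 to 2810 around 2045, and for c4 against a4 1542 to 2659 around 2079. For r4 against MOPS 1472 became 953 with the single r5 library, and leaving out 1 library gave 926 (r4 replicate 2) to 1328. For MOPS against M9 347 became 532 with a term for the sequencing set and 131 to 366 without 1 library (131 without MOPS replicate 2, 147 without M9 replicate 1), where the lone library left is assumed to vary like the others. Differences between replicates correlated above 0.1 in 47 of 78 pairs of groups (median 0.190, range -0.324 to 0.917, 0.401 for a4 with M9, 0.282 for r4 with MOPS and 0.0702 for c4 with M9). Part of the groups thus varied together by set, but not all, so the sets were not treated as pairs. Of 72 list tests, 32 passed camera, 1 with an estimated correlation, 51 with fry, 31 with the term for the set and 29 without the titrated genes in the lists. The growth-rate slopes of the C-limitation fell from 1424 to 868 genes without the reference libraries, a fit with fewer samples. For the other changes in these counts the cause was not tested.

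Under median-of-ratios scaling, log2 changes in a4 reversed for trpS (-0.20), serS (-0.24), crr (-0.20), ptsH (-0.36), lpd (-0.13), rnr (-0.0852), hfq (-0.41), hupA (-0.31), ihfA (-0.34) and ompX (-0.30), as the scaling moved all genes by about -0.74. It also left 962 slopes in the reference rifampicin course, 167 in the C-limited one and 6 differences.

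After rifampicin, 2 to 11 min gave 957 slopes in the C-limited course. The 70 differences became 42 with 0 to 5 min (10 of them among the 70), 16 with 2 to 11 min, 14 with 1 to 7 min and 0 with 0 to 3 min by limma (355 unadjusted), with fewer samples in each. Without 1 time point they were 13 (9 min) to 85 (11 min). Slopes over 0 to 3 min reversed for flgJ (0.28), flgH (0.0212), murF (0.0310), rpoB (0.14) and for the difference of fepA (-0.0285). The correlation of slopes between courses, 0.824, moved to 0.895 with 0 to 5 min, 0.755 with 2 to 11 min and 0.902 with 0 to 3 min. That of slope with abundance, -0.261, moved to -0.0116, to -0.405 with a pseudocount of 10, and reversed to 0.110 with 0 to 3 min. The cause was not tested. The correlation of C- and A-limitation changes, 0.260, moved to 0.188 and 0.0874 with MOPS as reference of the A- and of the C-limitation, which removes the shared libraries, and to 0.212 with a filter of 20 ppm.

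For 532 named values, 6446 results under alternatives kept their direction and side of the threshold in 6007 cases, were weaker in 392, stronger in 32 and reversed in the 15 named above. Rescaling the rifampicin libraries to stable non-coding RNAs and shares without those RNAs were not run, since 0 of them are in the table. The depth, which was not inferred from the fractions, limits what can be said of genes near 0.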

Other observations

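The test of operon order in this part, and the genes singled out from the overlap of all 3 limitations, were chosen only after values had been seen.

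Across the 3 slowest conditions, 29 genes were lower and 63 higher in each, where independent calls would give 14.04 and 59.6. Given the overlap of the C- and A-limitation, which share the M9 libraries, an independent R-limitation would give 42.5 and 84.6, so the counts are no sign of a response common to all 3. Of the 29, the methionine synthase gene metE changed by -2.51 ± 0.25, -3.11 ± 0.25 and -1.04 ± 0.25 on the log2 scale (± SE, limma) in c4, a4 and r4, and the purine gene purD by -1.17 ± 0.19, -1.72 ± 0.19 and -1.31 ± 0.19. The pyrimidine gene pyrE changed by -1.05 ± 0.33, -1.44 ± 0.33 and -1.52 ± 0.33 and glmS of amino sugar synthesis by -1.41 ± 0.23, -0.83 ± 0.23 and -1.88 ± 0.23. The tryptophan genes trpA and trpB, the spermidine genes speD and speE, the copper and silver efflux gene cusF and the uracil permease gene uraA were also among the 29. Under median-of-ratios scaling all 29 stayed below 0 in each limitation and 26 were still called in all 3.

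Among the 63, the stress sigma factor gene rpoS rose by 2.13 ± 0.20, 3.06 ± 0.20 and 0.61 ± 0.20, the glycerol phosphate transport gene ugpB by 3.48 ± 0.27, 1.55 ± 0.27 and 0.71 ± 0.27, and the phosphate-binding protein gene pstS by 0.75 ± 0.28, 1.48 ± 0.28 and 0.87 ± 0.28. Of the phage shock genes pspB rose by 1.02 ± 0.29, 1.09 ± 0.29 and 2.43 ± 0.29, while pspA rose in r4 (1.95 ± 0.21) and had log2 changes of 0.11 ± 0.21 and 0.38 ± 0.21 in c4 and a4 (limma adjusted p = 0.718 and 0.135). Under median-of-ratios scaling 33 of the 63 were still called in all 3, 57 stayed above 0 and 61 were tested, and dksA, a regulator of transcription, had -0.26 in a4 in place of 0.52.

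Genes late in long operons fell later after rifampicin. In the reference course flgB, first of its operon, changed by -2.60 on the log2 scale from 0 to 2 min and flgJ, the last, by 1.05. The same was seen from fliF (-6.57) to fliK (0.78), from atpI (-4.70) to atpC (0.72), from trpE (-1.79) to trpA (0.83) and from rplK (-0.40) to rpoC (0.56). In 12 of 12 operons the change from 0 to 2 min rose with the position in the operon in both courses (exact sign test p = 0.000488, median rho 0.983 and 0.980). The flg and rplK to rpoC operons were chosen knowing early changes of some members, the other 10 from general knowledge. A candidate explanation is that RNA polymerases already transcribing at the time of the drug go on to reach late genes, so that early slopes of such genes may understate their decay. With 1 library per time point this stays a hypothesis.

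Among other values, lpp made up 39.8% of the transcripts at 11 min of the reference course and rmf 22.2% at 11 min of the C-limited course.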
